A study of Caenorhabditis elegans with 6 samples.

How the data were processed

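MicroRNA levels were measured on 6 one-colour arrays, 1 for each of 2 strains of the nematode Caenorhabditis elegans under 3 exposures. Per the labels' protocols, about 100000 dauer larvae (a stress-resistant arrested stage) were loaded per container, flown for 16.5 days at 23 °C and collected 7 h after landing, and 1 µg of total RNA per sample was labelled with the dye Hy3. The strains were the wild type N2 and a strain labelled as a ced-1 mutant; ced-1 encodes a receptor for the engulfment of dying cells. The labels disagree on the mutant's strain name: titles and source names give LS292, and the strain characteristic gives MT4930, so the group is called the mutant labelled ced-1. LS292 is better known as the name of a strain with a mutation in dys-1, the worm dystrophin gene, so the mutant's genotype stays open. The exposures were a static slot in flight (radiation dose 1.92 mGy, gravity peaks up to 0.01 g), a 1 g centrifuge slot in flight (2.27 mGy) and a static slot on the ground, run 2 days later.

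The deposited tables give the intensity of each spot as foreground and as foreground minus local background, per the file headers. A further table by the authors gives intensity per probe and a normalized intensity, per the file headers; the rule behind the normalization factor is not given in the sources used here. The 3 mutant arrays stand in 1 raw table and the 3 N2 arrays in another with older probe names, so strain and table cannot be told apart. A value table of the series holds the authors' normalized intensity too, but its columns match the expression table only after reordering: each of its 6 columns equals, within a relative tolerance of 0.0001, the values that the expression table gives for another sample. Its column medians, under the labels it carries, are 0.541, 0.341 and 0.106 for N2 static, centrifuge and ground and 0.176, 0.118 and 0.325 for the mutant. Sample names of the raw tables were used throughout. A total of 12 other value columns, 6 of them the authors' ratios and the rest foreground per probe, were not used here. Scale and centring of the series value table are those of the authors' normalized intensity. The sample descriptions give the sample names of the raw tables, and the labels of the series value table go against them. Why they differ is unknown.

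Each array held 10080 spots for 2314 probe identifiers, with 4 spots per worm probe. The design fixed before the data were examined called for the spots of a probe to be averaged. The median of the 4 spots was used in place of the mean. That choice was made after the tables were opened and before any comparison was computed, because the median equals the authors' value per probe on 2314 of 2314 probes of each array (tolerance 0.01). The mean of the spots is an alternative added later, and it moves several results.

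Background-subtracted intensity was scaled by each array's median over the 8 worm probes at an intensity of 50 or more on all 6 arrays, set to a floor of 50 and put on the log2 scale. Of 156 worm probes, 128 reached 50 on at least 2 arrays and were tested. Probe names are those of the newer table; 145 of the 156 have a gene symbol in the WBcel235 gene table, which was used for names only, since no genome build is named for the array. No miRNA had more than 1 probe; miR-44-3p and miR-45-3p share 1.

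Exposure and strain effects were tested with limma 3.58.1 in R 4.3.3, with an additive model of strain and exposure, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. In that model the strains serve as the replicates of an exposure. Per the series' design text, repeats were technical and not of samples, so p-values measure only the spread between these arrays. Within a strain 1 array stood against 1, so differences have no test and no p; miRNAs were counted when they differed at least 2-fold and were detected on at least 1 of the arrays. The error given beside such a difference is a technical SE from the 4 spots of each array. Of 17 lists of miRNAs fixed before the data were examined, 13 with at least 2 measured members were tested with limma's camera at a preset correlation of 0.01 and with an estimated one; within a strain, a list's median was placed among 10000 random lists matched on mean level. The miRNAs named were chosen by a rule fixed before the data were examined. For each tested comparison these are up to 10 with the smallest adjusted p past 0.05, and the 10 largest rises and falls among those changed at least 2-fold the same way in every strain (or every exposure). For each difference within a strain these are the 5 largest rises and the 5 largest falls among detected miRNAs; members of the lists may be named too. A miRNA at the floor on 1 side is given as at least N-fold, with the value of the other side taken as exact. limma's estimates take a value at the floor as measured.

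The fit was tested on simulated data for the static minus ground comparison over 128 miRNAs with 20 changed, in 20 draws. It recovered 9.25% of 2-fold changes, 92.0% of 4-fold changes and 100% of 16-fold changes. The simulated values had the same noise for every miRNA (SD 0.47 on the log2 scale), no floor, and the full change in both strains. Changes in 1 strain only, or cut by the floor, were not simulated, so these rates do not apply to them. Noise that differs between miRNAs was not simulated either, so the rates can be too high for the real arrays. There miR-81-3p was over 4-fold lower in both strains for this comparison (-2.18 and -2.20), and limma did not call it (SE 0.89, adjusted p = 0.891). Alternatives covered normalization (quantile, 75th percentile, the authors' values), normexp background correction, floors of 20 and 100, the detection filter, probe annotation, model terms, size rules and leaving out each array. Added after seeing the data were the mean of the spots, detection above the control probes, subtraction of the control-probe level, scaling within each strain and a size rule that asks the brighter side to exceed the control probes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.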

Results

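The series asked how spaceflight, with and without simulated gravity, changed miRNA levels in wild-type worms and in a strain labelled as a ced-1 mutant. The number of arrays, 1 per strain and exposure, limits the precision of every value. Worm miRNAs were bright on the mutant arrays and dim on the N2 arrays. The brightest worm probe read 3388 (static), 10498 (1 g centrifuge) and 18658 (ground) in the mutant, against 505, 479 and 367 in N2. Of 156 worm probes, 53, 91 and 36 exceeded the 95th percentile of the control-probe spots on the mutant static, centrifuge and ground arrays, and 27, 31 and 30 did so on the matching N2 arrays. The control-probe median was 53, 38 and 64 on the mutant arrays, so the detection limit of 50 lay at the non-specific level there; on the N2 arrays it was -1, 5 and -8. The 4 spots of a probe varied most on the ground arrays: among worm probes at 200 or more, the median spot SD on the log2 scale was 0.29, 0.17 and 1.58 on the mutant static, centrifuge and ground arrays. On the N2 arrays it was 0.64, 0.48 and 2.20 in that order, over 3, 3 and 4 probes.

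**Figure D1:**
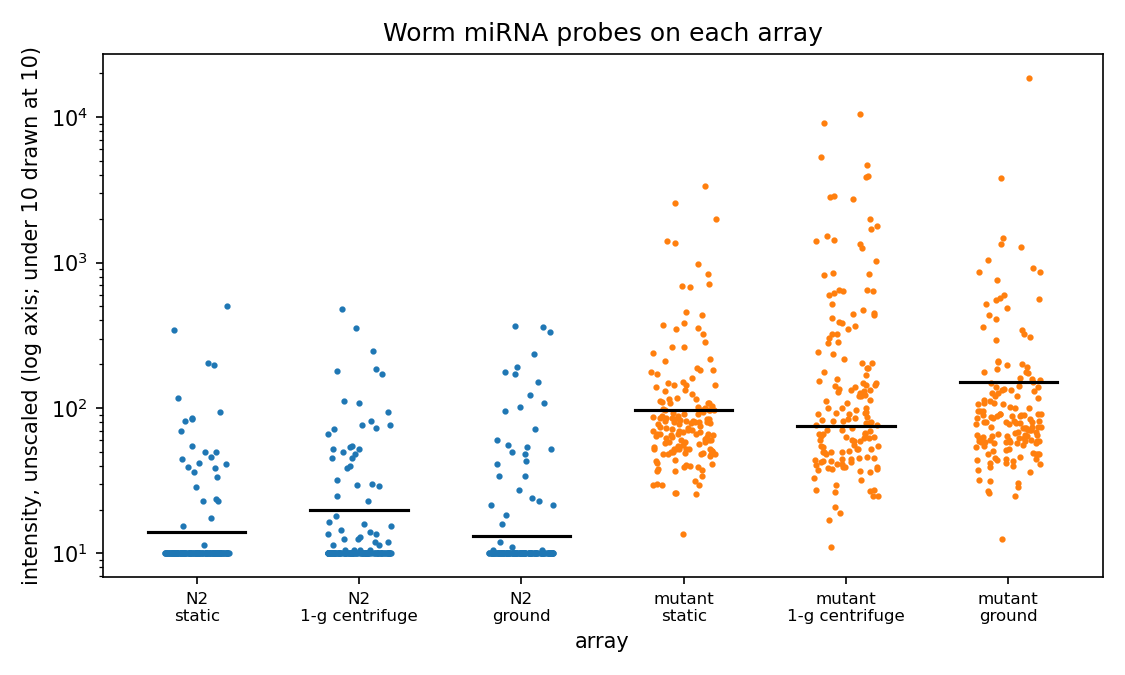
Unscaled intensity (log axis) of 156 worm miRNA probes on each of the 6 arrays, 1 point per probe, with values under 10 drawn at 10; the black line is the 95th percentile of the control-probe spots. The brightest probe reached 505 on an N2 array and 18658 on a mutant array.

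In the mutant, static flight against ground gave higher miR-71-5p, a regulator of lifespan and stress resistance, at a scaled intensity of 5049 against 798 (log2 difference 2.66, technical SE 0.32). miR-257 read 2952 against 186 (3.99, technical SE 0.28), and miR-58-3p 1012 against 144 (2.82, technical SE 0.68; 0.78 with the mean of the spots). miR-81-3p, of the abundant miR-58/bantam family, was lower in flight, at 3827 against 17294 (-2.18, technical SE 0.23; -1.03 under quantile normalization). miR-260 (3.14, technical SE 0.87) and the shared miR-44-3p/miR-45-3p probe (2.35, technical SE 1.00) were also higher. The other lower miRNAs were miR-35-3p (-2.74, technical SE 1.02), miR-228-5p (-2.38, technical SE 1.32), miR-73-3p (-1.50, technical SE 0.75) and miR-253-3p (-1.46, technical SE 0.36). The lower values of miR-35-3p, miR-228-5p and miR-253-3p, at 77.5, 91.7 and 71.5 in static flight, and that of miR-260, at 121 on the ground, lay under the control-probe limit. miR-260 came to 0.95 with the mean of the spots and miR-253-3p to -0.87 with normexp. The 4 static spots and the 4 ground spots lay apart for 5 of these 10 miRNAs, namely miR-257, miR-58-3p, miR-71-5p, miR-81-3p and miR-253-3p. For miR-44-3p/miR-45-3p the direction turned with the mean of the spots (-0.59).

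**Figure D2:**
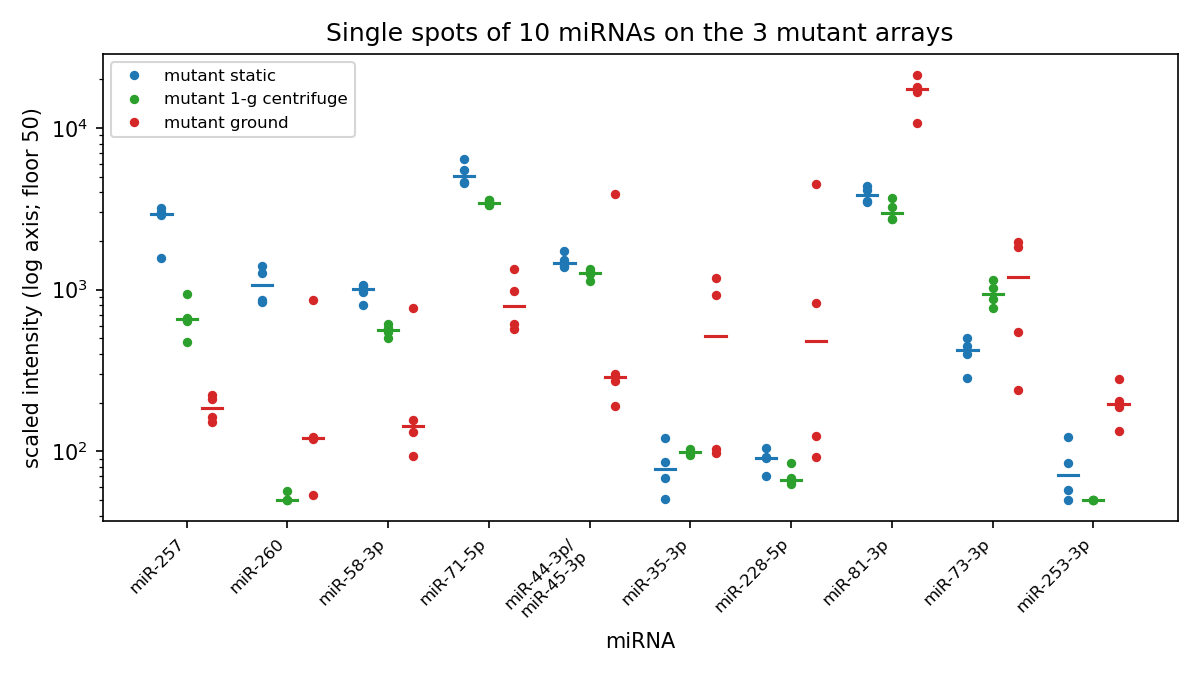
Scaled intensity (log axis, floor 50) of each of the 4 spots for 10 miRNAs on the 3 mutant arrays, with bars at the medians. The ground spots of miR-71-5p, at 567 to 1349, lay below its static spots, at 4571 to 6442, while those of miR-228-5p ran from 92 to 4528.

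Among the lists, members of the miR-35 family, which acts in embryonic development, gave a median log2 difference of -0.39 in the mutant between static flight and ground, with 1 of 6 measured members at least 2-fold higher and 3 lower. That median lay at percentile 0.95 of matched random lists, against a median of 0.55 over all compared miRNAs. The family median stayed below 0 under quantile, 75th percentile, the authors' and within-strain scaling and was 0.14 with no detection filter. miR-42-3p and miR-40-3p lay under the control-probe limit on both arrays, miR-35-3p and miR-37-3p in static flight and miR-39-3p on the ground. The family median thus rests partly on values at the non-specific level. The let-7 family, which times larval development, had 1 member higher and 2 lower of 7; let-7-5p read 480 against 966 (-1.01, technical SE 0.28), and ran from -2.04 with the mean of the spots to -0.66 with the control-probe level subtracted, above -1 also with the authors' values (-0.91). miR-34-5p, known from responses to DNA damage, read 254 against 88.1 (1.53, technical SE 0.13), where the ground value lay under the control-probe limit; it came to 0.55 with the mean of the spots and 0.97 with normexp. lin-4-5p read 262 against 131 (1.00, technical SE 0.48) with the ground value likewise under that limit, and came to -0.090 with the mean of the spots. The miR-44 family median was 1.46, with 2 of 3 members higher, and turned to -0.91 with the mean of the spots. The muscle miRNA miR-1-3p read 279 against 130 (1.10, technical SE 1.46), the ground value again under that limit, and turned to -3.13 with the mean of the spots. In all, 35 of 127 compared miRNAs were at least 2-fold higher and 10 lower. The split was 15 and 18 under quantile normalization, 14 and 15 under 75th percentile scaling and 21 and 14 with scaling within each strain. With the mean of the spots it turned to 5 and 45.

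In N2, static flight against ground gave higher miR-795-5p (1.54, technical SE 0.68), which turned to -1.19 with the mean of the spots, and miR-1822-3p, at least 2.76-fold higher. miR-258 was at least 15.8-fold lower, miR-256 at least 5.40-fold lower and lsy-6, which sets the asymmetry of a pair of taste neurons, at least 4.43-fold lower. These bounds take the ground value as exact, though the spots of the N2 ground array varied most. miR-265 differed by -2.03 (technical SE 0.74) and miR-81-3p by -2.20 (technical SE 1.20), which turned to 0.77 with the mean of the spots. In all, 2 of 20 compared miRNAs were at least 2-fold higher and 8 lower; with detection above the control probes the split turned to 16 and 6, and the median from -0.79 to 1.10. Across strains, 5 miRNAs differed at least 2-fold in both, and miR-1822-3p and miR-81-3p did so in the same direction. The mutant ground value of miR-1822-3p lay under the control-probe limit. In limma's additive model, 0 of 128 miRNAs passed an adjusted p of 0.05 for static flight against ground, and 3 had an unadjusted p under 0.05. The estimates were 1.55 for miR-1822-3p (SE 0.59, adjusted p = 0.891) and -2.19 for miR-81-3p (SE 0.89, adjusted p = 0.891). With the test restricted to the 8 miRNAs detected on all arrays, miR-257 passed (2.40, SE 0.75, adjusted p = 0.0464). None of the 13 tested lists passed with camera, and 0 members of any list passed when adjusted over the list alone.

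Between the 1 g centrifuge flight and ground, the mutant again gave higher miR-71-5p, at 3457 against 798 (2.11, technical SE 0.30), and miR-257, at 656 against 186 (1.82, technical SE 0.25). miR-81-3p read 2999 against 17294 (-2.53, technical SE 0.24). The values for miR-58-3p (1.97, technical SE 0.68), miR-793 (1.68, technical SE 0.29) and miR-44-3p/miR-45-3p (2.15, technical SE 1.00) were above 0; with the mean of the spots they came to 0.34, 0.97 and -0.51. The ground value of miR-793, at 63.5, lay under the control-probe limit. Those for miR-228-5p (-2.84, technical SE 1.31), miR-35-3p (-2.38, technical SE 0.98), miR-788-5p (-2.27, technical SE 0.87) and miR-38-3p (-2.12, technical SE 0.98) were below 0. The flights share 1 ground array, so the directions they have in common against it are not independent. In all, 12 of 120 miRNAs were at least 2-fold higher and 25 lower, and 16 of these 37 had 1 side at the floor. The split was 16 and 15 under quantile normalization, 14 and 12 under 75th percentile scaling, 22 and 10 with the authors' values and 10 and 61 with scaling within each strain. With the mean of the spots it was 4 and 71.

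In N2, the centrifuge flight against ground gave higher miR-788-5p (1.98, technical SE 0.62), and miR-1824-5p and miR-235-3p, at least 2.89- and 2.86-fold; both came to about 0 with normexp (-0.033 and -0.012). miR-237-5p differed by 1.65 (technical SE 0.71) and miR-56-3p by 1.41 (technical SE 0.71), and both were below 0 under 75th percentile scaling. miR-256 was at least 5.40-fold lower, miR-265 at least 4.76-fold, lsy-6 at least 4.43-fold and miR-82-3p at least 3.16-fold, again with the N2 ground value taken as exact. Across strains, 9 miRNAs differed at least 2-fold in both and 3 in the same direction: miR-234-3p, lsy-6 and miR-82-3p. The mutant ground values of miR-234-3p and lsy-6 lay under the control-probe limit. In limma's model 0 of 128 miRNAs passed and 1 had an unadjusted p under 0.05; miR-82-3p had an estimate of -1.42 (SE 0.44, adjusted p = 1.00) and lsy-6 of -1.74 (SE 0.69, adjusted p = 1.00). The neuron list of 4 members had a median estimate of -0.74 and camera adjusted p = 0.0341. Of its members, 0 passed, over all miRNAs or adjusted over the list alone. On the mutant ground array all 4 lay under the control-probe limit of 150. Before scaling, miR-124-3p read 126 there, miR-273 107, lsy-6 135 and miR-791-3p 149. In N2, 2 of the 4 were at the floor on both arrays, so a fall of neuronal miRNAs is not shown. The adjusted p of the neuron list was 0.723 with an estimated correlation.

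Static flight against the 1 g centrifuge flight compares the gravity conditions in orbit, at radiation doses of 1.92 and 2.27 mGy. In the mutant, miR-260 was at least 21.3-fold higher in static flight and miR-353 at least 5.45-fold. miR-788-5p differed by 2.66 (technical SE 0.09), miR-269 by 2.55 (technical SE 0.17) and miR-257 by 2.17 (technical SE 0.31). The scale factors were 1.49 for the static and 0.33 for the centrifuge array, and the technical SEs do not cover the scaling. Before scaling, miR-257, itself 1 of the 8 scaling probes, read 1980.5 and 1993.5, so its 2.17 rests on the scaling. The unscaled static and centrifuge values were 263 and 188 for miR-788-5p, 262 and 202.5 for miR-269 and 183 and 130 for miR-353. Their differences thus rest largely on the scaling too. miR-260 read 713.5 and 84.5 unscaled. The lowest values were those of miR-73-3p (-1.16, technical SE 0.22), miR-241-5p (-0.95, technical SE 0.20), miR-84-5p (-0.93, technical SE 0.22), miR-37-3p (-0.88, technical SE 0.33) and miR-230-3p (-0.52, technical SE 0.77); the static value of miR-37-3p lay under the control-probe limit. miR-241-5p and miR-84-5p belong to the let-7 family, whose median was -0.07 at percentile 0.84 of matched random lists, against 0.85 over all compared miRNAs. The family median was below 0 under every scaling tried and 0.05 with normexp. Its members let-7-5p and miR-84-5p are among the 8 scaling probes. The family median was -0.95 against 0.42 over all miRNAs with the authors' values and -0.07 against 1.71 with a floor of 20. It was -0.16 against 0.18 with the control-probe level subtracted and 0.00 against 0.20 with a floor of 100, so the gap depends on the processing. miR-71-5p (0.55, technical SE 0.12) and miR-81-3p (0.35, technical SE 0.13) differed less here than either flight did from ground, and both turned below 0 with 75th percentile scaling (-0.23 and -0.42) and the authors' values (-0.33 and -0.53). In all, 50 of 127 miRNAs were at least 2-fold higher and 1 lower, and 41 of these 51 had 1 side at the floor. The split was 8 and 5 under both quantile normalization and 75th percentile scaling, and 26 and 8 with the authors' values. The brighter side exceeded the control probes for 17 of the higher miRNAs and for the lower one.

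In N2, miR-795-5p was at least 4.34-fold higher in static than in centrifuge flight, and miR-258 at least 9.45-fold lower, miR-255-3p at least 3.66-fold and miR-73-3p at least 2.97-fold lower. miR-81-3p differed by -2.82 (technical SE 1.17) and turned to 0.77 with the mean of the spots. miR-73-3p was the 1 miRNA that differed at least 2-fold in the same direction in both strains. In limma's model 0 of 128 miRNAs passed and 0 had an unadjusted p under 0.05; the estimate for miR-73-3p was -1.37 (SE 0.55, adjusted p = 0.821). miR-260 passed with normexp background correction (2.28, SE 0.60, adjusted p = 0.0207) and with scaling within each strain (2.46, SE 0.63, adjusted p = 0.0162). Before scaling, miR-260 read 8.5, -14 and 10.5 on the N2 static, centrifuge and ground arrays, and all 3 were at the floor under the main scaling. Its difference therefore lies in the mutant arrays, and a change shared by both strains is not shown. The miR-72 family of 3 members had camera adjusted p = 0.00448 in the lower direction, with a mean estimate of -0.45 but a median of 0.00 and 0 members past the threshold. Its adjusted p was 0.722 with an estimated correlation and 0.832 under quantile normalization.

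Between the strains, 25 miRNAs passed as higher in the mutant and 1 as lower, of 128 tested, across 3 arrays per strain. miR-71-5p was at least 48.1-fold higher (log2 5.59, SE 0.60, adjusted p = 0.00347), and miR-48-5p of the let-7 family at least 32.9-fold (5.04, SE 0.35, adjusted p = 0.00181). The 4 measured members of the miR-58/bantam family all passed as higher, among them miR-82-3p (at least 4.94, SE 0.36, with 2 N2 arrays at the floor), miR-81-3p (4.66, SE 0.73) and miR-80-3p (at least 11.1-fold). miR-61-3p, miR-44-3p/miR-45-3p, miR-66-5p, miR-65-5p and miR-64-5p were at least 16.2-, 16.2-, 13.3-, 11.7- and 6.41-fold higher, miR-85-3p differed by at least 3.46 on the log2 scale, and miR-90-3p by at least 2.58 (SE 0.33, with 1 N2 array at the floor). Each was higher in the mutant in 3 of 3 exposures. The naming rule asks this of the largest rises, so for those it adds no support. miR-90-3p turned to -0.24 with 75th percentile scaling. The miRNA that passed as lower was miR-1823 (-2.67 or lower, SE 0.49, adjusted p = 0.0187), lower in 3 of 3 exposures; its mutant centrifuge value was at the floor, and its static and ground values, at 107 and 55.6, lay under the control-probe limit. Of the 26, 19 were at the floor on all 3 N2 arrays. For these the N2 values had no spread, so the error rests on the mutant arrays, and SE and adjusted p can be too small. Camera gave adjusted p = 0.0141 for the miR-58/bantam family; its adjusted p was 0.642 with an estimated correlation. All N2 arrays come from 1 raw table and all mutant arrays from the other, so strain and table cannot be told apart. Leaving out either array of an exposure gives the same strain test, with fewer residual degrees of freedom. Such fits therefore cannot show which array the calls rest on. The split turned to 8 higher and 89 lower with normexp, 8 and 10 under quantile normalization and 14 and 16 under 75th percentile scaling. With detection on all 6 arrays, 1 passed as higher (miR-84-5p, 1.95) and 1 as lower (miR-1823, -2.67). The count was 4 with a floor of 100 and 71 with scaling within each strain, all higher. It was 0 with the series value table as labelled, whose columns mix the strains by the raw tables' sample names.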

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

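The tests of signal share, of total foreground, of probe correlation between arrays, of spot overlap, of scaling and of other array splits were chosen or worked out only after the result was seen; the count of probes in foreground was written before.

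The first pattern is that worm probes were dark on the N2 arrays. Lower labelling or scanner gain would lower worm probes and probes with no name in the tables alike. The worm share of signal above the control probes was 1.71%, 1.98% and 1.01% on the N2 static, centrifuge and ground arrays against 5.65%, 12.5% and 14.6% on the mutant arrays, a ratio of means of 6.98, which argues against gain as the whole cause. Gain as a part stays open, since the Hy3 dye spots had medians of 602, 642 and 682.5 on the N2 static, centrifuge and ground arrays against 3129.5, 2893.5 and 2900.5 on the mutant arrays. With no background subtracted, the total worm foreground above the control probes was 1992, 1525.5 and 2946.5 on the N2 arrays against 17591, 70872.5 and 30966.5 on the mutant arrays, a ratio of means of 18.5. The median worm foreground lay 3.5, 2 and 2.5 over the control median on the N2 arrays and 24.75, 54.5 and 24 over it on the mutant arrays. These values argue against local background subtraction as the whole cause. The count written before did not part the strains on the ground: in foreground 13, 15 and 24 worm probes exceeded the control probes on the N2 arrays against 50, 89 and 24 on the mutant arrays, where the ground limits were 102.25 and 338. RNA of another source, another array batch and a strain difference cannot be told apart, since each strain lies in 1 table. Across unnamed probes, which are not independent replicates, arrays of different strains correlated at 0.665 at most and arrays within a table at 0.670 to 0.948. Across worm probes, arrays of different strains correlated at 0.272 to 0.355 and arrays within a table at 0.744 to 0.870.

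The second pattern is the set of 10 named static minus ground differences in the mutant. All 10 kept their direction under 4 other scalings, but they had been picked for size: the smallest was 1.46, and the scalings moved their median by 0.42 or less, so a turn was hardly possible and the scaling between arrays stays open. A single factor per array moves all miRNAs alike, so it cannot by itself give both the 3.99 of miR-257 and the -2.18 of miR-81-3p. Disagreement between the spots of the mutant ground array stays open: the static and ground spots lay apart for 5 of the 10, and the ground spots of miR-228-5p ran from 92 to 4528. A response of the mutant to flight was not tested, with 1 array per exposure.

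The third pattern is the 26 miRNAs called between the strains. The 6 arrays have 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 26 calls, the highest of the others 0, and 1 split of the 10, the real one, gave as many. Every other split mixes the strains, so the strain difference enters its error and holds its calls down. With exposure kept as a term, some splits also rest on the arrays of 1 exposure. The other splits are therefore not like the real one, and no conclusion is drawn from them.

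Probes with no name in the tables, which no comparison used, exceeded the control-probe limit 427 times on the mutant static array and 567 times on the mutant centrifuge array, above the 192 on the mutant ground array. The limits differed, at 97, 75.25 and 150 in that order, and at a fixed intensity of 50 the counts ran the other way, at 1512, 1059 and 1692. In N2 the counts above the limit were 488 and 534 in flight and 536 on the ground.

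Several miRNAs differed at least 2-fold in opposite directions in the strains, and none of these differences was tested. For static flight minus ground, the mutant value exceeded the N2 value by at least 3.73 on the log2 scale for miR-256, with values at the floor, and by 2.37 for miR-796, and the mutant minus N2 value was -2.55 for miR-795-5p. The mutant values of miR-256 and miR-796 lay under the control-probe limit on both arrays, and both mutant differences were 0.00 under quantile normalization. With the mean of the spots miR-795-5p fell in both strains (-2.71 in the mutant, -1.19 in N2). For centrifuge flight minus ground, mutant minus N2 values were -4.26 for miR-788-5p and -2.94 for miR-56-3p and, with values at the floor, -3.40 or lower for miR-1824-5p and -2.88 or lower for miR-235-3p. The mutant ground value of miR-235-3p lay under the control-probe limit, so its -2.88 is not a firm bound. miR-788-5p alone kept opposite directions under all 12 alternatives, though its N2 value was 0.01 with normexp; miR-56-3p fell in both strains with 75th percentile scaling (-1.17 in the mutant, -0.31 in N2) and with the mean of the spots (-3.25 and -1.78). The N2 values of miR-1824-5p and miR-235-3p came to -0.033 and -0.012 with normexp. For static minus centrifuge flight, mutant minus N2 values were at least 3.04 for miR-255-3p and 3.06 for miR-235-3p, again with values at the floor. The mutant static value of miR-255-3p lay under the control-probe limit, so its 3.04 is not a firm bound. With the control-probe level subtracted, its mutant difference was 0.00. Under quantile normalization miR-255-3p was lower in both strains (-0.08 in the mutant, -3.03 in N2), and with scaling within each strain the N2 value of miR-235-3p was 0.00.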

How the results depend on the processing

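Detection above the control probes, subtraction of the control-probe level, the mean of the spots, scaling within each strain and the size rule on the brighter side were chosen after seeing the data. Unless stated, the cause of a shift was not tested. By the raw tables' sample names, the columns of the series value table hold other arrays than labelled. Its mutant centrifuge and ground columns, for example, equal the N2 static and N2 ground arrays. Counts and medians given for it therefore compare other arrays, some across strains, and do not measure a change of processing. The exposure comparisons in limma kept 0 calls except 1 for static flight minus ground with the 8 miRNAs detected on all 6 arrays, where fewer were tested, and 1 for static minus centrifuge flight with normexp and 1 with scaling within each strain; they stayed at 0 without each array in turn. The 26 calls between strains became 97 with normexp, 51 with a floor of 20, 4 with a floor of 100, 2 with detection on all 6 arrays, 71 with scaling within each strain, 0 with the series value table as labelled, and 0 to 10 without each array in turn. With an array left out, 1 exposure has a lone array, assumed to vary like the rest. Of the 26, 9 were called in the same direction under quantile normalization, 14 under 75th percentile scaling, 25 with the authors' values and 9 with normexp. Camera's 1 call each for centrifuge flight minus ground, static minus centrifuge flight and mutant minus N2 became 0, 0 and 0 with an estimated correlation; under quantile normalization the last became 2 and static minus centrifuge flight 0. The counts of miRNAs changed at least 2-fold are given next, where they moved by over 1.5 times. In the mutant, the 45 for static flight minus ground became 29 with 75th percentile scaling, 15 with normexp, 22 with a floor of 100, 3 with detection on all 6 arrays, 28 with detection above the control probes, 77 at 1.5-fold and 9 at 4-fold. The 37 for centrifuge flight minus ground became 8 with the series value table, 86 with normexp, 82 with a floor of 20, 17 with a floor of 100, 2 with detection on all 6 arrays, 75 with the mean of the spots, 24 with the control-probe level subtracted, 71 with scaling within each strain, 24 with the brighter side above the control probes, 58 at 1.5-fold and 7 at 4-fold. The 51 for static minus centrifuge flight became 13 with quantile normalization, 13 with 75th percentile scaling, 85 with normexp, 83 with a floor of 20, 8 with a floor of 100, 3 with detection on all 6 arrays, 22 with the mean of the spots, 21 with detection above the control probes, 11 with the control-probe level subtracted, 79 with scaling within each strain, 18 with the brighter side above the control probes, 91 at 1.5-fold and 6 at 4-fold. In N2, the 10 for static flight minus ground became 61 with the series value table, 0 with normexp, 6 with a floor of 100, 0 with detection on all 6 arrays, 22 with detection above the control probes, 17 at 1.5-fold and 5 at 4-fold. The 13 for centrifuge flight minus ground became 39 with the series value table, 0 with normexp, 7 with a floor of 100, 2 with detection on all 6 arrays, 21 with detection above the control probes, 8 with the control-probe level subtracted, 7 with scaling within each strain and 3 at 4-fold; its split of 9 higher and 4 lower became 1 and 14 with 75th percentile scaling. The 6 for static minus centrifuge flight became 10 with quantile normalization, 11 with 75th percentile scaling, 35 with the series value table, 0 with normexp, 3 with a floor of 100, 0 with detection on all 6 arrays, 12 with the mean of the spots, 12 with detection above the control probes, 15 at 1.5-fold and 3 at 4-fold. With the mean of the spots, static flight minus ground turned to -0.59 for miR-44-3p/miR-45-3p, -0.91 for the miR-44 family median -0.090 for lin-4-5p and -3.13 for the muscle miRNA miR-1-3p in the mutant, and to -1.19 for miR-795-5p and 0.77 for miR-81-3p in N2. Centrifuge flight minus ground turned to -0.51 for miR-44-3p/miR-45-3p and -0.91 for the miR-44 family median in the mutant and to -1.78 for miR-56-3p in N2, and static minus centrifuge flight to 0.77 for miR-81-3p in N2. In N2, centrifuge flight minus ground turned to -0.067 for miR-237-5p and -0.31 for miR-56-3p with 75th percentile scaling, and to -0.033 for miR-1824-5p and -0.012 for miR-235-3p with normexp; miR-90-3p between strains turned to -0.24 with 75th percentile scaling. The median over detected miRNAs in the mutant, 0.55, -0.34 and 0.85 for the 3 comparisons in the order above, was 0.00, 0.00 and 0.00 under quantile normalization, 0.03, 0.00 and 0.05 with 75th percentile scaling and 0.26, -0.99 and 1.16 with scaling within each strain; for static flight minus ground it turned to -0.71 with the mean of the spots and -0.46 with detection on all 6 arrays. For centrifuge flight minus ground it turned to 0.20 with the series value table and 0.07 with the control-probe level subtracted, and was -1.32 with normexp, -1.15 with a floor of 20 and -1.09 with the mean of the spots. In N2 the median of -0.79 for static flight minus ground turned to 1.10 with detection above the control probes, where the split became 16 higher and 6 lower, to 1.08 with the series value table and to 0.43 with detection on all 6 arrays. The N2 median of 0.60 for centrifuge flight minus ground turned to -1.12 with 75th percentile scaling, -0.56 with the control-probe level subtracted, -0.28 with scaling within each strain and -0.03 with normexp. That of -0.73 for static minus centrifuge flight turned to 0.52 with 75th percentile scaling, 0.61 with the series value table and 0.03 with normexp. In the mutant the mean of the spots also took static flight minus ground from 2.82 to 0.78 for miR-58-3p, from 3.14 to 0.95 for miR-260 and from 2.66 to 1.62 for miR-71-5p, and centrifuge flight minus ground from 1.97 to 0.34 for miR-58-3p, from 1.68 to 0.97 for miR-793, from 2.11 to 1.36 for miR-71-5p and from 1.82 to 1.25 for miR-257. Quantile normalization took miR-81-3p to -1.03 in both. In the mutant, static minus centrifuge flight turned to -0.23 and -0.42 for miR-71-5p and miR-81-3p with 75th percentile scaling and to -0.33 and -0.53 with the authors' values. Static flight minus ground went from 1.53 to 0.55 with the mean of the spots and 0.97 with normexp for miR-34-5p, and from -1.01 to -0.91 with the authors' values, -0.91 with normexp, -0.86 with detection above the control probes and -0.66 with the control-probe level subtracted for let-7-5p. The miR-35 family median for static flight minus ground was 0.14 with no detection filter, and the let-7 family median for static minus centrifuge flight 0.05 with normexp. The series value table was run for counts and medians, not for named miRNAs or lists. Signal over background limits the N2 values, with 11, 19 and 17 of 156 worm probes at 50 or more on the static, centrifuge and ground arrays.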

Other observations

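Some biology of the mutant arrays lies outside the comparisons above. let-7-5p read 480 in static flight, 504 in centrifuge flight and 966 on the ground, and miR-72-5p read 271, 270 and 99.2 in that order, where the ground value lay under the control-probe limit. The near-equal values in both flights hold under the main scaling: static minus centrifuge flight was -0.07 for let-7-5p and 0.00 for miR-72-5p there, but -0.84 and -0.77 with 75th percentile scaling and -0.95 and -0.88 with the authors' values. miR-48-5p read 2017, 1765 and 1253, with a technical SE of 0.94 for static flight minus ground (0.69), which came to -1.79 with the mean of the spots. miR-235-3p, known from starvation arrest, read 145 in static flight and 129 on the ground, the latter under the control-probe limit, and was under the floor in centrifuge flight.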
